A study of Mus musculus with 9 samples.

How the data were processed

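RNA of mouse uterus was sequenced by the submitters in 9 libraries, 3 per group: uterine horns injected with unconditioned embryo culture medium (control), with pooled medium of 9 developmentally competent human embryos, or with pooled medium of 18 arrested human embryos. Per the labels, C57BL/6 females of 25 days had received progesterone (1 mg) and estradiol (10 mg/kg per day) for 3 days, and 50 µl of medium was injected per horn. The design text gives 21 days as the age, and which is right was not settled. The time between injection and collection, and whether each library came from a different animal, are not given in the sources used here. Libraries were made from 1 µg of RNA with a TruSeq kit and sequenced on an Illumina HiSeq instrument.

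Per the submitters' processing notes, reads were aligned to mm9 with Bowtie 0.12.2 and transcripts were assembled and quantified with Cufflinks. The Cufflinks version and options are not given in the sources used here. The deposited transcript values are FPKM by the authors, with the ends of their confidence intervals, and the deposited coverage signal is the mean read depth over each transcript, not divided by library size. The tables of control library 1 had no header line, so columns were taken by their order in the other libraries. Each library listed 92839 annotated transcripts and a further set assembled in that library; 98.9% of the annotated transcripts had the coordinates of GENCODE vM1 on NCBIM37, and 1356 were not in that reference and were not used. Between 64.5 and 66.3% of transcripts were listed at 0 in a library.

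Gene values were computed with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and bedtools 2.31.1. The value of a gene was the sum of FPKM over its annotated transcripts and over assembled multi-exon transcripts that share a splice junction with that gene and no other; assembled transcripts made up 4.96% of gene FPKM in the median library. FPKM were used as deposited, without rescaling; median-ratio size factors computed from them ranged from 0.955 to 1.05. Depth in reads is unknown. Coverage times transcript length amounted to 1303 Mb in control library 1, the lowest, and 2471 Mb in competent library 1, the highest, and coverage per FPKM ranged from 1.09 to 1.98. A gene of low FPKM is therefore measured on few reads, and its estimate can fall to 0 by the division of reads among transcripts.

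Of 14252 genes with a mean of at least 1 FPKM over the 9 libraries, 945 were left out as failed estimates, listed at 0 in some but not all libraries of a group whose other libraries averaged over 5 FPKM. This filter used the group labels. Genes with zeros in part of a group were left out, whereas genes with zeros throughout a group were kept. It can therefore favour calls that follow the groups. The remaining 13307 genes were tested in R 4.3.3 with limma 3.58.1 on log2(FPKM + 1), in 1 fit of the 9 libraries with group means, empirical Bayes moderation with a mean trend (8.95 total degrees of freedom, 2.95 of them prior), 3 contrasts and an F test over the groups. Benjamini-Hochberg adjustment was made over all genes tested within each contrast, with a threshold of 0.05. Of the genes tested, 42 were listed at 0 in every library of at least 1 group; these were kept, and are described by each library's value. An estimate of the spread from 3 libraries per group is imprecise. Tested on simulated data with 200 changed genes in 3 simulations, the fit recovered 54.7% of changes of log2 1 and 86.3% of changes of log2 2, and called a mean of 8.67 unchanged genes. The changed genes were drawn from those with a mean log2(FPKM + 1) above 3, and simulated genes varied independently. Recovery at lower FPKM was not simulated.

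The gene lists, the tests, the thresholds and the main alternatives were fixed before the data were examined. Of 43 lists, 39 had at least 3 tested members and were tested with limma camera at a preset correlation between genes of 0.01, and again with the correlation estimated from the data; adjusted p-values are over the lists of a contrast. Eosinophil (2 members), ovary and oviduct (2), urothelium (1) and skeletal muscle (1) markers were not tested. For members of a list, p-values were also adjusted over the list alone. Named genes followed a fixed rule. In each contrast these were the called genes with non-overlapping groups and the largest differences, up to 10 per direction. Where fewer passed, those of smallest unadjusted p filled the places and are described as not past the threshold. Up to 4 members of each list with the smallest p were eligible, and Hspa5, Ddit3, Atf4, Xbp1, Herpud1, Hspa8, Lif, Hbegf, Ptgs2, Scnn1a and Sgk1 were named whatever their p. Predicted genes known only by an identifier were counted and not named. The value of 1 gene that the rule made eligible is not reported here.

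Overlap of the 2 responses was set beside 1000 simulated pairs of unchanged groups that share 3 controls, with equal spread and, chosen after seeing the data, with the spread of each group, and beside the product of the 2 counts of called genes divided by the number tested. Regroupings of the libraries used all 10 splits of each pair of groups and 100 of the 280 splits into 3 groups. The 26-nucleotide Xbp1 intron was read from the annotation. The form without it was taken as a share of the summed FPKM of that form and an annotated form that keeps it. Shares were compared by an exact permutation test.

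Alternatives covered a pseudocount of 0.1, no filter, a filter at 5 FPKM, size factors, quantile normalization, only the groups compared, arrayWeights, no trend, a robust trend, failed estimates kept, the transcript of highest mean FPKM per gene, and each library left out, with an alternative block by replicate number described in the closing part. Added after the data were seen were annotated transcripts only, mean coverage over exons, protein-coding genes only, and genes at 0 in a whole group left out. Exon coverage of a gene was the mean depth over its exons from all listed transcripts on its strand or without a strand, divided by the coverage per FPKM of the library. Read-level data were not used here.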

Results

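Transcripts of whole mouse uterus were measured by RNA sequencing in 9 libraries from hormone-primed C57BL/6 females. The horns had received unconditioned embryo culture medium (control), medium conditioned by developmentally competent human embryos, or medium conditioned by human embryos that had arrested (n = 3 libraries per group). Values were FPKM for 35934 genes, of which 13307 were tested (12084 protein-coding). Depth in reads is unknown, and the coverage values amount to 1303 to 2471 Mb of sequence in transcripts per library. The labels do not state that the libraries of a group came from separate animals or from separate pools of medium. Every p-value therefore measures the spread between these samples, which may be partly technical. Differences are given as log2 differences of FPKM + 1 ± SE, a scale that understates genes of low FPKM. Library profiles correlated at r = 0.937 to 0.975 within groups and 0.930 to 0.970 between groups, across genes that are not independent replicates. Arrested libraries 1 and 2 correlated less with their own group (mean r = 0.945 for each) than with the other groups (0.954 for each). Arrested library 3 was at 0.938 and 0.934, and every control and competent library correlated more with its own group. Arrested library 3 stood apart, at 58.2 on the leading principal component (23.7% of the variance), where the other 8 libraries lay between -21.6 and 10.1. Arrested library 2 differed in composition: the adipocyte genes Fabp4 and Car3 stood at 598 and 238 FPKM there and at no more than 82.4 and 34.4 in the other 8 libraries. Its scores relative to all 9 libraries were 3.46 for adipocyte, 0.76 for stromal fibroblast and -0.43 for epithelium markers.

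Single genes of differing function separated the 2 conditioned media. Arg1, the urea cycle arginase that also serves polyamine synthesis, stood at 68.9 ± 17.8 FPKM after competent and 12.1 ± 3.26 after arrested embryo medium, with controls between them at 26.3 ± 1.62 (mean ± SD, n = 3). Lcn2, the secreted siderophore-binding lipocalin of estrogenized uterine epithelium, went from 3863 ± 211 to 932 ± 343 FPKM against 2345 ± 313 in controls. Muc4, a membrane mucin of the luminal surface, went from 80.5 ± 13.9 to 22.4 ± 3.68 FPKM (controls 53.4 ± 6.15). Ddit4, a stress-induced inhibitor of mTORC1, stood at 124 ± 10.8 FPKM after competent and 50.6 ± 2.84 after arrested embryo medium, and Elf3, an epithelial ETS transcription factor, at 417 ± 41.9 and 179 ± 32.5. Cd83, a surface protein of activated dendritic cells and lymphocytes, went the other way, from 1.22 ± 0.196 to 6.91 ± 0.668 FPKM (controls 4.09 ± 0.823). Srgn, the proteoglycan of leukocyte granules, was at 62.9 ± 2.18 FPKM after competent and 158 ± 13.4 after arrested embryo medium, beside 148 ± 20.7 in controls.

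In the moderated test, the arrested minus competent difference was -2.41 ± 0.23 for Arg1 (limma adjusted p = 0.0049), -1.80 ± 0.18 for Muc4 (0.0059), -2.11 ± 0.24 for Lcn2 (0.014), -1.27 ± 0.16 for Ddit4 (0.020) and -1.23 ± 0.16 for Elf3 (0.023). Naip1, an inflammasome sensor of bacterial proteins, fell by 1.55 ± 0.17 (32.2 ± 3.13 to 10.5 ± 2.22 FPKM, limma adjusted p = 0.0087). Itgam, the integrin of neutrophils and macrophages, differed by -2.22 ± 0.32, and Abp1, the diamine oxidase of decidualizing uterus, by -1.71 ± 0.25 (limma adjusted p = 0.035 for each). The adhesion receptor Gpr128 (-1.98 ± 0.27), the airway-type serine protease Tmprss11d (-1.70 ± 0.24) and the Golgi protein Golm1 (-1.51 ± 0.23) were also lower, as were Padi1, a citrullinating enzyme under estradiol control (-1.28 ± 0.19), and Cfb, the alternative complement protease (-1.21 ± 0.18). Smaller falls were those of the clock repressor Bhlhe40 (-1.19 ± 0.18), the acid sphingomyelinase Smpd1 (-1.18 ± 0.15), the rhomboid protease Rhbdl2 (-1.14 ± 0.15), the channel kinase Trpm7 (-1.12 ± 0.18), the lipid transfer protein Tex2 (-1.02 ± 0.15) and the tropomyosin Tpm3 (-0.98 ± 0.14). Exon coverage differed less for Trpm7 (7.30 ± 0.416 after competent and 6.03 ± 1.47 after arrested embryo medium, in FPKM units) and Rhbdl2 (4.55 ± 1.3 and 2.84 ± 0.254), so these calls depend on how reads were divided among transcripts. The transcripts of Tpm3 and its retrocopy Tpm3-rs7 are near-identical, so the call of Tpm3-rs7 is uncertain.

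Among the genes that were higher after arrested embryo medium, Cd83 rose by 1.83 ± 0.18 (limma adjusted p = 0.0059) and Srgn by 1.31 ± 0.14 (limma adjusted p = 0.0076). Coch, a secreted cochlin matrix protein, went from 0.589 ± 0.441 to 17.2 ± 11.3 FPKM (3.38 ± 0.40, limma adjusted p = 0.016), with controls at 4.91 ± 1.12. Wnt11, a non-canonical WNT ligand of the uterine epithelium, went from 4.31 ± 3.23 to 49.5 ± 28.7 FPKM (3.29 ± 0.49, limma adjusted p = 0.035; controls 13.8 ± 3.66). Scel, a cornified envelope precursor, rose by 1.81 ± 0.27, Ntn4, a basement membrane netrin, by 1.37 ± 0.20, the lymphocyte membrane protein Ms4a4b by 1.10 ± 0.16 and the laminin chain Lama2 by 1.00 ± 0.15. Asna1, the ATPase that delivers tail-anchored proteins to the endoplasmic reticulum, rose in FPKM by 1.28 ± 0.18 (46.3 ± 3.62 to 116 ± 29.0). Its exon coverage scarcely differed, at 46.3 ± 3.62 and 54.8 ± 9.27 in FPKM units, so the call of Asna1 depends on how reads were divided among transcripts. Exon coverage of Lama2 was 2.07 ± 0.157 and 3.79 ± 1.80, also a smaller difference than in FPKM. Positions on NCBIM37 are 10:24635014-24647276 for Arg1 (ENSMUSG00000019987), 2:32240153-32243317 for Lcn2 (ENSMUSG00000026822), 16:32735972-32782477 for Muc4 (ENSMUSG00000079620), 13:43880476-43898499 for Cd83 (ENSMUSG00000015396) and 10:61956581-61990199 for Srgn (ENSMUSG00000020077).

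In all, 39 genes differed between arrested and competent embryo medium past a limma adjusted p of 0.05, 17 higher and 22 lower after arrested embryo medium, and 8 of these were listed at 0 in a whole group. At unadjusted p under 0.05 there were 1776 genes (13.3%). The 3 libraries of each group did not overlap for 18.8% of genes, where 10% is the mean expected over splits of the libraries. Genes vary together, so a single split can lie far from that mean, and the share was not set beside other splits. The count of genes past the threshold was 139 without arrested library 2, 64 without arrested library 3, 22 without competent library 3 and 18 without competent library 2. It was 19 when failed estimates, left out by a rule that uses the group labels, were kept. Arg1, Muc4, Cd83 and Naip1 kept their calls with each library left out in turn. The call of Arg1 was lost when only annotated transcripts were summed (limma adjusted p = 0.23) and with the transcript of highest mean FPKM (0.19), with a difference of -1.90 in both, although its exon coverage was 77.5 ± 8.26 after competent and 12.1 ± 3.26 after arrested embryo medium. Without competent libraries 2 and 3 in turn, the limma adjusted p was 0.058 and 0.054 for Lcn2 and 0.067 and 0.056 for Coch. Without competent libraries 1, 2 and 3 in turn it was 0.063, 0.052 and 0.082 for Ddit4 and 0.053, 0.11 and 0.082 for Elf3 (limma adjusted p). Other calls were lost more readily. Without competent library 2 the limma adjusted p was 0.15 for Itgam, Abp1, Tmprss11d, Scel and Padi1 and 0.14 for Gpr128 and Wnt11. Without competent library 3 it was 0.13 for Itgam, 0.099 for Abp1, 0.14 for Tmprss11d, 0.15 for Scel and Wnt11, 0.17 for Padi1 and 0.12 for Gpr128 (limma adjusted p). Without competent library 1 it was 0.080 for Itgam, Abp1, Tmprss11d and Gpr128 and 0.090 for Padi1 (limma adjusted p). Leaving out arrested library 1 or 3, or a control library, also ended some of these calls, with limma adjusted p between 0.053 and 0.079. Other settings ended calls too. With the transcript of highest mean FPKM alone, Scel differed by 0.87 (limma adjusted p = 0.35), Tmprss11d by -1.03 (0.47), Itgam by -1.96 and Gpr128 by -1.81 (0.19 each). With annotated transcripts only, the limma adjusted p was 0.48 for Tmprss11d, 0.22 for Gpr128, 0.083 for Itgam and Scel, 0.088 for Padi1 and 0.058 for Elf3. Over all settings, the call of Padi1 was lost in 14 of 25, those of Wnt11 and Abp1 in 11 and those of Itgam and Gpr128 in 10, and those of Scel and Tmprss11d in 13 and 11 of 24. Elf3 lost its call in 6 of 25, Ddit4 in 4, Lcn2 and Coch in 3, and Naip1 in 1 of 23.

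**Figure D1:**
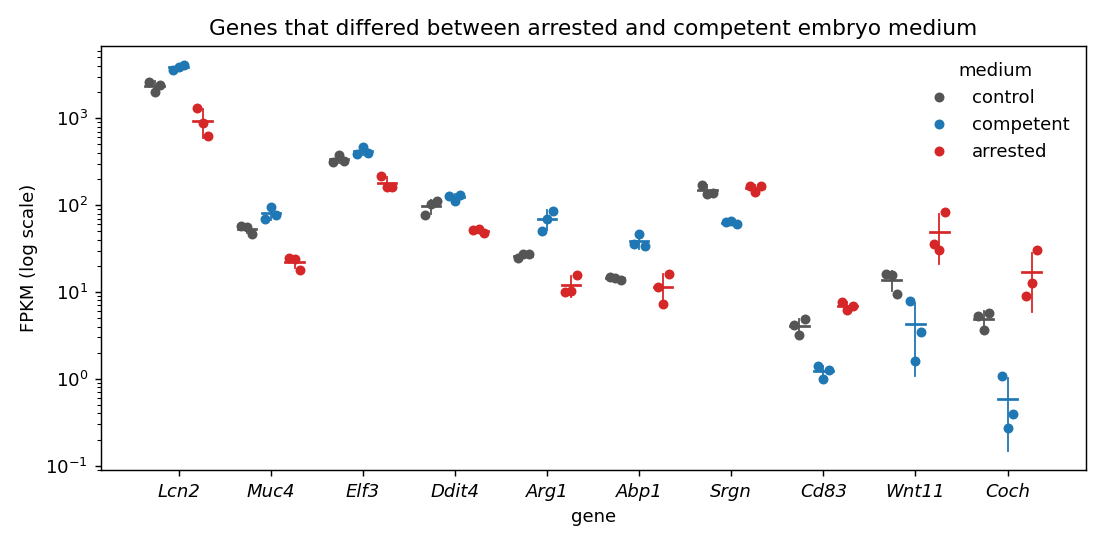
FPKM on a log axis of 10 genes in the 9 libraries, by group; dots are libraries, bars are group means and lines are ± SD (n = 3). Arg1, Lcn2 and Muc4 are lowest after arrested embryo medium (12.1, 932 and 22.4 FPKM), whereas Srgn and Cd83 are lowest after competent embryo medium (62.9 and 1.22 FPKM).

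Estradiol-responsive uterine genes were the only list that differed between the conditioned media under both settings of the list test. Their mean score per library relative to all 9 libraries was 0.26, 0.31 and 0.33 after competent embryo medium, 0.08, 0.11 and -0.05 in controls, and -0.27, -0.32 and -0.46 after arrested embryo medium. Of 26 members, 21 were lower and 5 higher after arrested than after competent embryo medium (median -0.86). Besides Muc4, Lcn2 and Padi1, the 3 members past the threshold over all genes (Padi1 not in 14 of 25 other settings), 10 more were lower when adjusted over the list alone. They were the cell cycle inhibitor Cdkn1a (-1.32 ± 0.22), the milk iron-binding protein Ltf (-1.20 ± 0.23; 3119 ± 473 to 1389 ± 430 FPKM), complement C3 (-1.0 ± 0.21), the gap junction protein Gjb2 (-1.94 ± 0.52), Padi2 (-1.76), Igf1 (-1.14 ± 0.35), Mcm2 (-0.72), the calcium-activated channel regulator Clca3 (-2.05), and Sprr2f and Sprr2a1. The Sprr2 genes are near-identical copies, so the values of Sprr2f (-1.88 ± 0.43) and Sprr2a1 (-1.71) are uncertain. Adjusted over the list alone, the retinoic acid hydroxylase Cyp26a1 (3.09 ± 1.06) and the thioredoxin inhibitor Txnip (0.94 ± 0.34) were higher. The receptors themselves were not past either threshold, with 0.22 ± 0.23 for Pgr and -0.29 ± 0.32 for Esr1.

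The estradiol list was called lower after arrested than after competent embryo medium by limma camera (adjusted p = 2.52e-08; adjusted p = 0.0207 with an estimated correlation). Against control, 20 of the 26 members were lower after arrested embryo medium (median -0.48; limma camera adjusted p = 3.29e-05; adjusted p = 0.0586 with an estimated correlation). After competent embryo medium 17 were higher than in control and 9 lower (median 0.38; limma camera adjusted p = 0.00155; adjusted p = 0.198 with an estimated correlation). Adjusted over the list alone, Muc4 (-1.22 ± 0.18), Lcn2 (-1.39 ± 0.24), Padi1 (-1.01 ± 0.19), Padi2 (-1.62), Cdkn1a (-0.82 ± 0.22) and Padi4 (-0.51) were lower after arrested embryo medium than in control, and no member was past that threshold between competent embryo medium and control.

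**Figure D2:**
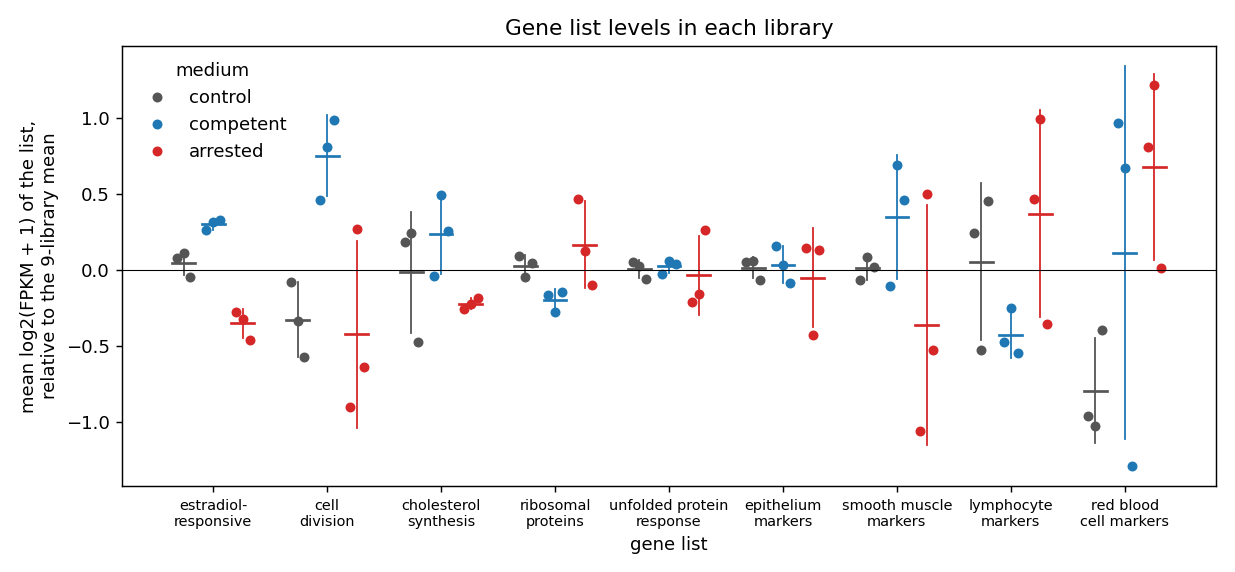
Mean log2(FPKM + 1) of 9 gene lists per library, relative to the mean of all 9 libraries; each dot is a library and colour marks the group (n = 3). The estradiol list separates the 3 groups without overlap (group means 0.30, 0.05 and -0.35), while cell division after arrested embryo medium ranges from -0.90 to 0.27.

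Cell division genes were highest after competent embryo medium. The mitotic kinase Plk1 stood at 2.16 ± 0.117 FPKM in controls, 9.55 ± 4.01 after competent and 2.32 ± 1.93 after arrested embryo medium (n = 3), and the survivin gene Birc5 at 7.44 ± 2.38, 25.9 ± 9.11 and 7.15 ± 4.87. Cdk1, the kinase of mitotic entry, stood at 23.5 ± 4.81, 76.3 ± 18.5 and 37.4 ± 27.7 FPKM, and Rrm2, the ribonucleotide reductase subunit, at 4.33 ± 1.22, 11.2 ± 2.78 and 3.36 ± 1.68. All 26 members were higher after competent embryo medium than in control (median 1.12) and all 26 were lower after arrested than after competent embryo medium (median -1.16). By limma 0 passed the threshold over all genes, and 19 and 23 had an unadjusted p under 0.05 in these comparisons; adjusted over the list alone, 16 were higher in the former comparison and 23 lower in the latter. Examples from the former are Plk1 (1.67 ± 0.43), Cdk1 (1.64 ± 0.43), Ccna2 (1.76 ± 0.48) and Top2a (1.37 ± 0.43), and from the latter Rrm2 (-1.54 ± 0.33), Birc5 (-1.83 ± 0.44) and Ccne1 (-0.98 ± 0.24). The limma camera adjusted p was 4.38e-24 between competent embryo medium and control (adjusted p = 0.409 with an estimated correlation) and 4.41e-17 between the conditioned media (adjusted p = 0.778 with an estimated correlation). Between arrested embryo medium and control the median was -0.12, with 6 members higher and 20 lower (limma camera adjusted p = 0.64). Scores of the 3 libraries after arrested embryo medium were -0.90, 0.27 and -0.64.

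Further groups differed between the conditioned media with the preset correlation only. Cytosolic ribosomal protein genes were higher after arrested embryo medium (27 of 28 members; median 0.38; limma camera adjusted p = 3.46e-10; adjusted p = 0.835 with an estimated correlation). Cholesterol genes, with squalene epoxidase Sqle at -0.62 ± 0.30, were lower (15 of 16 members; median -0.44; limma camera adjusted p = 0.000123; adjusted p = 0.835 with an estimated correlation). Interferon response genes were lower in 17 of 22 members (median -0.28; limma camera adjusted p = 0.0101; adjusted p = 0.835 with an estimated correlation), with the nucleic acid sensor Zbp1 past the threshold adjusted over the list alone (-0.77 ± 0.16). Without arrested library 2 the limma camera adjusted p of the interferon list was 0.42, and with annotated transcripts only it was 0.095. Smooth muscle markers were lower in all 14 members (median -0.77; limma camera adjusted p = 0.000624; adjusted p = 0.835 with an estimated correlation), among them the contractile actins Actg2 (-1.27 ± 0.47) and Acta2 (-0.92 ± 0.43). Their scores after arrested embryo medium were -1.06, 0.50 and -0.53, and without arrested library 1 the limma camera adjusted p was 0.090. Lymphocyte markers were higher in 7 of 8 members (median 0.86; limma camera adjusted p = 0.00259; adjusted p = 0.835 with an estimated correlation), and the T cell adhesion receptor Cd2 (0.82 ± 0.22) passed when adjusted over the list alone. With only genes of at least 5 FPKM the limma camera adjusted p of the lymphocyte list was 0.14. Epithelium, macrophage and neutrophil markers were not called between the conditioned media (limma camera adjusted p = 0.312, 0.312 and 0.356).

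No gene of the unfolded protein response passed the threshold in any comparison. Hspa5, the ER chaperone BiP, stood at 357 ± 43.4 FPKM in controls, 294 ± 101 after competent and 257 ± 106 after arrested embryo medium (n = 3), with exon coverage of 142 ± 23.8, 138 ± 7.29 and 117 ± 22.0 in FPKM units. Atf4, the transcription factor translated under eIF2 alpha phosphorylation, was at 90.4 ± 1.83, 89.7 ± 9.03 and 87.5 ± 13.0 FPKM. Xbp1, the factor activated by IRE1 splicing, was at 89.3 ± 7.70, 66.1 ± 12 and 105 ± 43.7, and Herpud1, a component of ER-associated degradation, at 37.2 ± 6.54, 26.6 ± 1.39 and 37.9 ± 12.8. Ddit3, which encodes the pro-apoptotic factor CHOP, was listed at 0 in arrested library 1 and at 24.1 and 21.0 in the other 2, beside 19.3, 17.4 and 29.3 in controls and 14, 14.1 and 13.9 after competent embryo medium. Ddit3 was not tested because of that estimate.

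Against control, the difference after arrested embryo medium was -0.57 ± 0.36 for Hspa5 (limma adjusted p = 0.86), -0.06 ± 0.14 for Atf4 (0.98), 0.17 ± 0.26 for Xbp1 (0.95) and -0.01 ± 0.23 for Herpud1. After competent embryo medium it was -0.33 ± 0.36 for Hspa5 (limma adjusted p = 0.94), -0.02 ± 0.14 for Atf4, -0.44 ± 0.26 for Xbp1 and -0.46 ± 0.23 for Herpud1. Between the conditioned media it was -0.23 ± 0.36 for Hspa5, -0.04 ± 0.14 for Atf4, 0.61 ± 0.26 for Xbp1 (limma adjusted p = 0.36) and 0.45 ± 0.23 for Herpud1. The smallest unadjusted p of the list between arrested embryo medium and control belonged to Wfs1, an ER membrane protein (-0.47 ± 0.19; limma adjusted p = 0.76), followed by the ER co-chaperone Dnajb9 (0.41 ± 0.22; limma adjusted p = 0.85). Of 29 unfolded protein response genes 11 were higher and 18 lower (median -0.04); by limma 0 passed over all genes, 0 adjusted over the list alone, and 1 had an unadjusted p under 0.05. Between competent embryo medium and control 0 did, and between the conditioned media 2 did, Dnajb11 (-0.63 ± 0.21) and Xbp1. Scores of the list were -0.21, -0.16 and 0.26 in the 3 libraries after arrested embryo medium, the last the highest of all 9 libraries, with Xbp1 at 156 and Dnajb9 at 31.9 FPKM. The limma camera adjusted p was 0.911 against control, 0.444 between the conditioned media (8 higher, 21 lower, median -0.06) and 0.543 between competent embryo medium and control (17 higher, 12 lower, median 0.016).

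The Xbp1 form that lacks the 26-nucleotide intron was set against an annotated form that keeps it, and other Xbp1 transcripts were left out. Such a share follows how Cufflinks divided reads between the forms. Reads across the splice junction were not counted, so it is no direct measure of splicing in any library. The share of the form without the intron in the summed FPKM of both was 66.9, 70.6 and 56.6% in controls. It was 100, 100 and 69.5% after competent, and 68.1, 65.5 and 100% after arrested embryo medium. The difference from control was 25.1 percentage points after competent embryo medium (exact permutation p = 0.2) and 13.2 after arrested embryo medium (exact permutation p = 0.5), where 0.1 is the smallest possible. In the 3 libraries at 100% the other form was listed at 0, and whether that is splicing or an estimate that failed was not tested. In these libraries (competent 1, competent 2 and arrested 3) the form without the intron stood at 43.1, 53.2 and 123 FPKM. The gene totals were 54.0, 66.4 and 156 FPKM, with the rest in transcripts left out of that share.

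Heat shock and integrated stress response genes did not move as groups. Of 22 heat shock genes, 11 were higher and 11 lower after arrested embryo medium than in control (median -0.0024; limma camera adjusted p = 0.75, direction up although the median is below 0). Hspa8, the constitutive HSC70, differed by -0.06 ± 0.15 after arrested and -0.27 ± 0.15 after competent embryo medium, and the inducible Hsp90aa1 by -0.84 ± 0.32 after arrested embryo medium (limma adjusted p = 0.76). The heat shock list had a median of 0.10 between competent embryo medium and control (limma camera adjusted p = 0.344) and -0.0055 between the conditioned media (0.661). Integrated stress response genes, 22 in number, had medians of 0.018, -0.19 and -0.17 in the 3 comparisons (limma camera adjusted p = 0.438, 0.42 and 0.254). Within that list Ddit4 passed adjusted over the list alone, lower after arrested embryo medium than in control (-0.91 ± 0.16), and the pseudokinase Trib3 differed by 0.52 ± 0.23 (limma adjusted p = 0.80).

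**Figure D3:**
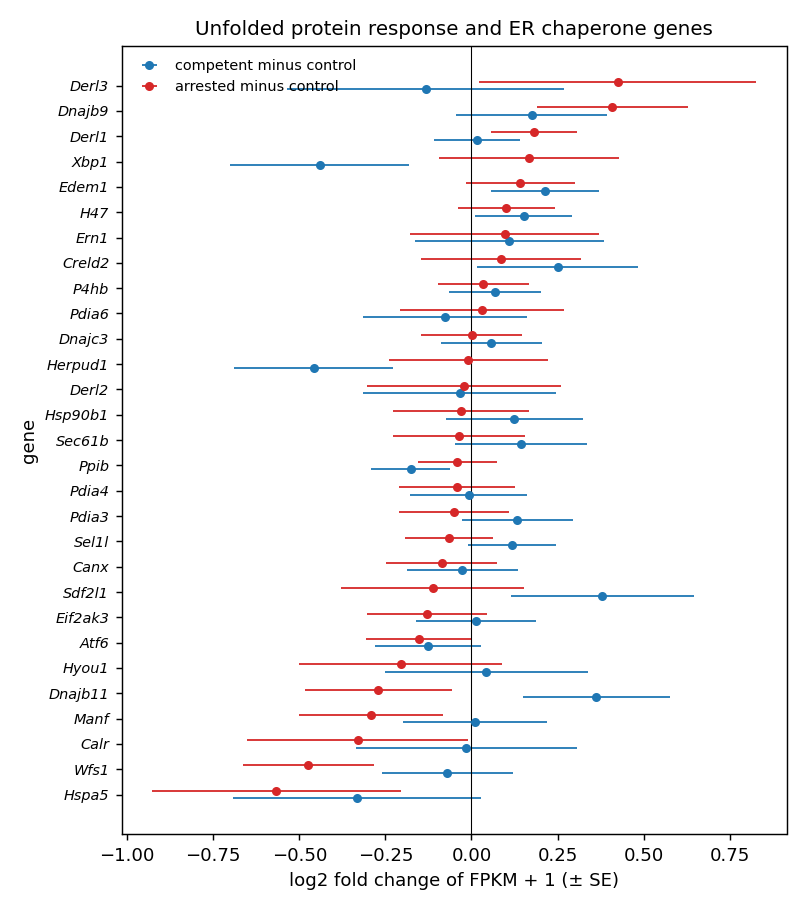
Log2 difference ± SE of 29 unfolded protein response genes against control, for competent and for arrested embryo medium (n = 3 libraries per group). Points scatter on both sides of 0, with medians of 0.016 and -0.04.

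Implantation factors moved in both directions between the conditioned media. Lif, the leukemia inhibitory factor that starts implantation in mice, stood at 1.88 ± 0.467 FPKM in controls, 2.42 ± 0.283 after competent and 1.05 ± 0.198 after arrested embryo medium (n = 3), whereas Ptgs2, the inducible prostaglandin synthase, stood at 0.554 ± 0.0241, 0.645 ± 0.0833 and 3.02 ± 2.18. Of 27 implantation and receptivity genes, 4 were higher and 5 lower after arrested than after competent embryo medium when adjusted over the list alone, and by limma 0 passed over all genes and 10 had an unadjusted p under 0.05. Higher were Ptgs2 (1.15 ± 0.35), the angiogenic factor Vegfa (1.09 ± 0.24), the stromal homeobox gene Hoxa11 (0.74 ± 0.21) and the progesterone-induced ligand Ihh (1.12 ± 0.34). Lower were Lif (-0.74 ± 0.20), the decidual ligand Wnt4 (-0.81 ± 0.16), the GATA factor Gata2 (-0.83 ± 0.20), E-cadherin Cdh1 (-0.54 ± 0.12) and the anti-adhesive mucin Muc1 (-1.43 ± 0.39). The limma camera adjusted p was 0.76 between the conditioned media (median 0.041, direction down), 0.759 between arrested embryo medium and control (median -0.13) and 0.871 between competent embryo medium and control (median 0.061). Hbegf, an epidermal growth factor ligand of the attachment site, differed by 0.14 ± 0.25 between the conditioned media, -0.09 ± 0.25 between arrested embryo medium and control, and -0.23 ± 0.25 between competent embryo medium and control.

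Few genes differed past the threshold between arrested embryo medium and control. Ubl4, a ubiquitin-like component of the tail-anchored protein pathway, stood at 77.9 ± 8.94 FPKM in controls, 23.8 ± 1.85 after competent and 27.0 ± 3.27 after arrested embryo medium (n = 3). It fell by 1.5 ± 0.14 after arrested and by 1.66 ± 0.14 after competent embryo medium (limma adjusted p = 0.0046 and 0.0076). Exon coverage of Ubl4 (X:71611057-71614012, ENSMUSG00000015290) differed far less, at 26.7 ± 0.541, 20.8 ± 1.61 and 23.5 ± 2.85 in FPKM units, and the transcript of highest mean FPKM went the other way (0.32 and 0.15). Genes named above lay below control without passing: Muc4 at -1.22 ± 0.18 (limma adjusted p = 0.10), Elf3 at -0.92 ± 0.16 and Ddit4 at -0.91 ± 0.16 (0.22 each), Lcn2 at -1.39 ± 0.24 and Tpm3 at -0.77 ± 0.14 (0.24 each), with Tex2 at -0.87 ± 0.15 and Rhbdl2 at -0.90 ± 0.15. Above control, also not past the threshold, were Scel at 1.59 ± 0.27 and Asna1 at 1.10 ± 0.18 (limma adjusted p = 0.22 each).

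In all, 8 genes differed between arrested embryo medium and control past a limma adjusted p of 0.05, 5 higher and 3 lower, and 7 of them were listed at 0 in a whole group. At unadjusted p under 0.05 there were 816 genes (6.13%), and groups did not overlap for 9.60% of genes, where 10% is the mean expected over splits. The count was 24 without control library 1, 23 without control library 2, 18 without control library 3, 27 without arrested library 2 and 22 without arrested library 3. Among gene lists, red blood cell genes were higher (5 of 5 members; median 1.59; limma camera adjusted p = 3.76e-05; adjusted p = 0.883 with an estimated correlation). Adjusted over the list alone, Hba-a1, Hba-a2 and Hbb-b2 passed; Hba-a1 (1.63) and Hba-a2 (1.64) are near-identical copies and their separate values are uncertain. Ribosomal protein genes were higher in 26 of 28 members (median 0.15; limma camera adjusted p = 0.000865; adjusted p = 0.977 with an estimated correlation), but without arrested library 1 the limma camera adjusted p was 0.99, and with quantile normalization it was 0.85 and the median -0.0033. Of 3 mitochondrially encoded transcripts tested, mt-Co1 (0.55) and mt-Co3 (0.50) passed adjusted over the list alone (limma camera adjusted p = 0.000997; adjusted p = 0.883 with an estimated correlation). Mesothelium markers (median 0.86; limma camera adjusted p = 0.0257; adjusted p = 0.977 with an estimated correlation) and uterine aquaporins, channels and transporters (median 0.15; limma camera adjusted p = 0.0404; adjusted p = 0.977 with an estimated correlation) were higher. Without arrested library 3 the limma camera adjusted p of these was 0.30 and 0.57, without control library 1 it was 0.077 and 0.15, and without control library 3 it was 0.21 and 0.12. Without arrested library 2 that of mesothelium was 0.17, and without competent library 1 that of the transporters was 0.057 and of the mitochondrial list 0.95, the latter with a turned camera direction and 4 members tested (limma camera adjusted p). The call of the transporters was lost in 14 of 25 settings, with limma camera adjusted p of 0.052 for genes of at least 5 FPKM, 0.058 with size factors, 0.055 with only the 2 groups and 0.34 with the transcript of highest mean FPKM (median 0.012). That of mesothelium was lost in 9 of 25 and that of the mitochondrial list in 5, with a turned direction when only the 2 groups were compared (limma camera adjusted p = 0.89).

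Many of the called genes were listed at 0 in a whole group. Sprr2g, a small proline-rich protein of cornifying epithelium, was listed at 0 in all 6 control and competent libraries and at 56.7, 64.2 and 70.8 FPKM after arrested embryo medium. March2, a membrane-bound ubiquitin ligase, was at 0 in the same 6 libraries and at 27.2, 19.4 and 33.0 after arrested embryo medium. The small nucleolar RNA Snord23 (319, 357 and 315) and the small Cajal body RNA SCARNA21 (23.8, 53.3 and 70.6) had the same pattern, although a transcript of that length is poorly measured in such libraries and SCARNA21 has near-identical copies. Syce2, a synaptonemal complex protein, was at 10.0, 10.7 and 6.59 in controls, 10.7, 13.9 and 16.4 after competent and 0 in all 3 libraries after arrested embryo medium. Trip13, a meiotic and spindle checkpoint ATPase, was at 0 in all 3 arrested libraries, 3.99, 4.39 and 5.22 after competent embryo medium, and 1.78, 0 and 1.10 in controls. Ube2v1, a ubiquitin-conjugating enzyme variant, was at 0 in all 3 controls, 20.8, 38.4 and 39.4 after competent and 15.2, 38.3 and 36.8 after arrested embryo medium. BC037034, 1 of a pair of near-identical genes, was at 9.14, 5.08 and 13.0 in controls and 0 in the other 6 libraries. After competent embryo medium, the zinc finger gene Zfp87 was listed at 0 (controls 6.15, 6.36 and 5.73; arrested 9.05, 7.19 and 2.64), as was Pbld2 (controls 2.15, 2.50 and 4.54; arrested 4.01, 3.06 and 2.50), whose exon coverage there was 0, 1.49 and 0 FPKM units. Exon coverage of Ube2v1 was 20.4 ± 5.45 FPKM units in controls and 26.1 ± 3.13 and 22.7 ± 3.39 after competent and arrested embryo medium, and Zfp87 and BC037034 had coverage in all 9 libraries. That coverage includes transcripts listed under other genes at the same place, so whether these genes were expressed in their groups at 0 stays open. The gene Tmem189 (ENSMUSG00000089739), which overlaps Ube2v1, stood at 33.2 ± 8.87 FPKM in controls, where Ube2v1 was at 0. Tmem189 was lower where Ube2v1 was listed, at 6.13 ± 10.6 after competent and 7.66 ± 6.66 after arrested embryo medium. The call of Ube2v1 may therefore reflect reads listed under Tmem189 in controls. Exons of Sprr2g, March2, Snord23, SCARNA21, Syce2 and Trip13 had no coverage in their groups at 0, though transcripts on the opposite strand were not counted. Exon coverage is summed from listed transcripts and not from reads, so an estimate that failed also gives 0, as for Ddit3 in arrested library 1. For these 6 genes it therefore cannot separate absent expression from a failed estimate. The calls of Zfp87, Pbld2 and Trip13 were lost without single libraries, with limma adjusted p up to 0.12 for Zfp87, 0.089 for Pbld2 and 0.15 for Trip13. With annotated transcripts only and with exon coverage, Pbld2 differed by 0.67 and 0.85 between the conditioned media (limma adjusted p = 0.70 and 0.28). The calls between the conditioned media were lost in 7 of 22 settings for Pbld2, 6 of 23 for Zfp87 and 11 of 23 for Trip13. Between the conditioned media, the limma adjusted p was 4.1e-09 for Snord23, 2.1e-07 for Sprr2g, 9.4e-05 for Syce2 and 0.035 for Trip13.

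**Figure D4:**
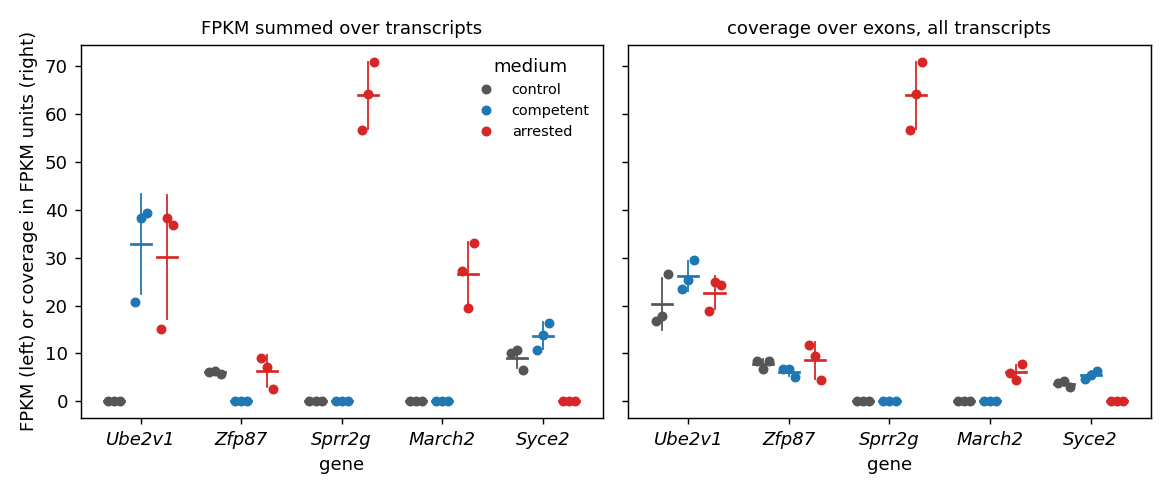
FPKM (left) and exon coverage in FPKM units (right) of Ube2v1, Zfp87, Sprr2g, March2 and Syce2; each dot is a library and colour marks the group (n = 3). Ube2v1 is listed at 0 FPKM in controls although its exons carry 20.4 units of coverage there, whereas Sprr2g has neither outside the arrested group.

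Few genes passed between competent embryo medium and control, among them the leukocyte proteoglycan Srgn. Srgn fell by 1.22 ± 0.14 (148 ± 20.7 to 62.9 ± 2.18 FPKM; limma adjusted p = 0.031), where exon coverage was 53.1 ± 7.53 and 23.1 ± 0.963 in FPKM units. Without competent libraries 1, 2 and 3 and control library 3 in turn, the limma adjusted p of Srgn was 0.071, 0.069, 0.083 and 0.056, and it was 0.062 with exon coverage and 0.13 with a replicate block (lost in 8 of 25 settings). Cd83, at 1.22 ± 0.196 FPKM beside 4.09 ± 0.823 in controls (n = 3), differed by -1.19 ± 0.18 without passing (limma adjusted p = 0.20). On the upper side, not past the threshold, were Trpm7 (1.13 ± 0.18; limma adjusted p = 0.20; exon coverage only 5.92 ± 0.624 in controls and 7.30 ± 0.416), Arg1 (1.33 ± 0.23; 0.27), Abp1 (1.36 ± 0.25; 0.35), Cfb (0.94 ± 0.18; 0.39) and Naip1 (0.84 ± 0.17; 0.41). On the lower side, also not past it, were Lama2 (-0.81 ± 0.15) and Ms4a4b (-0.86 ± 0.16). Sgk1, the serum- and glucocorticoid-induced kinase, stood at 79.3 ± 24.8 FPKM in controls, 32.9 ± 19.0 after competent and 54.8 ± 31.1 after arrested embryo medium, differences of -1.33 ± 0.46 and -0.61 ± 0.46 (limma adjusted p = 0.68 and 0.88). In all, 5 genes passed a limma adjusted p of 0.05, 1 higher (Ube2v1) and 4 lower (Srgn, Ubl4, Zfp87 and BC037034), and 784 had an unadjusted p under 0.05 (5.89%). Groups did not overlap for 17.2% of genes, where 10% is the mean expected over splits. A single split can lie far from that mean, so no excess is shown by it. Leaving out 1 library gave 16, 21 and 8 genes (controls 1, 2 and 3), 14, 12 and 12 (competent 1, 2 and 3) and 8, 15 and 9 (arrested 1, 2 and 3).

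Gene lists moved after competent embryo medium as well. Ribosomal protein genes were lower in 27 of 28 members (median -0.23; limma camera adjusted p = 1.51e-05; adjusted p = 0.936 with an estimated correlation), and cholesterol genes higher in 14 of 16 (median 0.24; limma camera adjusted p = 0.00824; adjusted p = 0.936 with an estimated correlation). Red blood cell genes were higher in 5 of 5 members, with library scores of 0.97, 0.67 and -1.29 (median 0.88; limma camera adjusted p = 0.00824; adjusted p = 0.936 with an estimated correlation). Smooth muscle markers were higher in all 14 (median 0.30; limma camera adjusted p = 0.0151; adjusted p = 0.936 with an estimated correlation), mesothelium markers in 7 of 8 (median 0.85; limma camera adjusted p = 0.0122; adjusted p = 0.936 with an estimated correlation) and extracellular matrix genes in 17 of 26 (median 0.27; limma camera adjusted p = 0.0456; adjusted p = 0.957 with an estimated correlation). Macrophage and monocyte markers were lower in 12 of 13 (median -0.34; limma camera adjusted p = 0.0122; adjusted p = 0.936 with an estimated correlation) and lymphocyte markers in 7 of 8 (median -0.67; limma camera adjusted p = 0.0341; adjusted p = 0.936 with an estimated correlation). Without control library 3 the limma camera adjusted p was 0.73 for cholesterol, 0.69 for macrophage, 0.36 for lymphocyte and 0.18 for mesothelium genes. Without control library 1 it was 0.11 for smooth muscle, 0.12 for lymphocyte and 0.26 for matrix genes, and without control library 2 it was 0.17 for matrix and 0.051 for red blood cell genes (limma camera adjusted p). Without competent library 1 it was 0.23 for red blood cell, 0.088 for macrophage, 0.10 for lymphocyte and 0.088 for mesothelium genes (limma camera adjusted p). Without competent library 2 it was 0.47 for smooth muscle, 0.23 for cholesterol and 0.070 for red blood cell genes (limma camera adjusted p). Without competent library 3 it was 0.21 for mesothelium, 0.64 for matrix, 0.14 for smooth muscle and 0.13 for lymphocyte genes, and without arrested library 3 it was 0.059 for matrix genes (limma camera adjusted p). With arrayWeights it was 0.35 for cholesterol (median 0.11), 0.20 for macrophage (-0.22) and 0.13 for lymphocyte genes (limma camera adjusted p). With no filter on low values it was 0.29 for lymphocyte (median -0.29) and for matrix genes (0.19; limma camera adjusted p). Over all 25 settings, the call was lost in 10 for lymphocyte, 9 for matrix, 5 for smooth muscle, 4 for cholesterol and for mesothelium, and 3 for macrophage and for red blood cell genes.

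The differences of the 2 conditioned media from control were no more alike than unchanged groups with shared controls. Across 13307 genes, which are not independent replicates, the differences of competent and of arrested embryo medium from the same controls correlated at r = 0.256 with a covariance of 0.0367. Unchanged groups of equal spread simulated against shared controls gave a mean r of 0.500 (0.454 to 0.540) and a mean covariance of 0.0581 (0.0503 to 0.0664). The arrested libraries spread more, with a mean variance of 0.252 beside 0.145 in controls and 0.125 after competent embryo medium. With each group's own spread, the simulated mean r was 0.444 (0.388 to 0.501) and the mean covariance 0.0485 (0.0422 to 0.0604). The observed values lay below these ranges, but simulated genes vary independently and real genes do not, so opposed responses are not shown by it. The 3 controls were not divided between the 2 comparisons, so the likeness was not checked with separate controls. Ube2v1 was higher in both comparisons (1 shared call where 0.000376 would be expected from 1 and 5), and Ubl4 and BC037034 were lower in both (2 shared where 0.000902 would be expected). The expected counts leave out the shared controls, and Ube2v1 was listed at 0 only there and BC037034 above 0 only there, so much of that excess may come from the shared controls. The exon coverage of these 3 genes differed little between groups. Over the 3 groups together, 18 genes passed the limma F test at an adjusted p of 0.05.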

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

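The tests of exon coverage, epithelium markers, residual correlations and regroupings were chosen after the results were seen, as was arrested library 3 as an explanation, although leaving out each library in turn was planned.

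Measures outside the comparisons exceeded the highest control library as follows. Transcripts shorter than 200 nucleotides held 9.12% of bases in competent library 1, 4.93% in competent library 3 and 4.82% in arrested library 1, where the highest control was at 4.12%. Assembled transcripts assigned to no gene held 7.52% of bases in competent library 1, against 6.41% in the highest control. Mitochondrial transcripts held 5.88% of bases in arrested library 1 and 5.07% in arrested library 3, against 4.64% in the highest control.

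Of the genes called in any comparison, 10 were listed at 0 in every library of at least 1 group. Zeros that fall on libraries at random could explain this: among sets of 3 libraries that are not a group, 22 of 81 held as many such genes as the arrested group, which held 5. For Ube2v1, Zfp87 and BC037034, listing under other transcripts at the same place is a likely explanation, since their exon coverage differed by a median of only 0.28 in absolute log2. No such listing was seen for the 6 genes without any coverage in the group at 0 (March2, SCARNA21, Snord23, Sprr2g, Syce2 and Trip13). Coverage counted only transcripts on the strand of the gene or without a strand, so listing on the opposite strand was not tested. It was summed from listed transcripts and not from reads, so it cannot separate absent expression from an estimate that failed. Whether reads were assigned differently among Sprr2 genes stays open for Sprr2g (mean 63.9 FPKM): Sprr2f was lower by 642 FPKM in the arrested libraries, but it also differed by 574 between competent and control libraries, where Sprr2g was at 0, and the summed Sprr2 FPKM fell by 617.

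Estradiol-responsive and cell division genes were lower after arrested than after competent embryo medium. A smaller share of epithelium cannot be told apart from it, since epithelium markers went both ways (median -0.072, from -1.23 to 1.01), with 4 of 17 lower and 0 higher by limma adjusted over the list alone. Their scores were 0.14, -0.43 and 0.13 in the arrested and 0.16, 0.03 and -0.09 in the competent libraries. Arrested libraries 1 and 3 thus lay within the competent range for epithelium, although their estradiol scores were -0.27 and -0.46. The estradiol list kept a median of -0.85 without arrested library 3, which stood apart. Its lower members did not vary together between libraries of a group (mean residual correlation 0.044), whereas those of the cell division list did (0.53). Members of a list can vary together within groups whatever set the groups apart. These values therefore do not decide whether variation between samples accounts for either list, and it stays open for both. Cell division scores were 0.46, 0.81 and 0.99 in the competent libraries and at most 0.27 in the others. Medium is the biological explanation that the design gives, but a difference in hormone priming between groups was not tested and would look the same in the estradiol list. Pools held 9 embryos for every competent and 18 for every arrested library, so embryo number cannot be told apart from competence. The labels do not state that libraries of a group had separate pools, so the libraries may not replicate embryos. Among regroupings of the competent and arrested libraries, the real split gave 39 genes and the highest other gave 10, so 1 of 10 splits reached the real count, too few splits for a share under 0.05.

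Unfolded protein response genes were not higher after arrested embryo medium as a group, although arrested library 3 had the highest score of all 9 libraries (0.26, against -0.21 and -0.16 in the other 2). Transcript estimates that hide a rise of Hspa5 are unlikely, since its exon coverage differed from control by -0.28 ± 0.17 on the log2 scale. A single library that hides a rise of the list was not found either, as the median lay between -0.17 and 0.032 with each library left out. A change before or after the time of collection, or in protein alone, was not tested.

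Chance cannot be told apart from treatment by the splits of either comparison with control, which are too few for a share under 0.05. For competent embryo medium against control the real split gave 5 genes and the highest other 7, with 6 of 10 splits reaching the real count. For arrested embryo medium against control the real split gave 8 and the highest other 11, with 5 of 10 reaching it. Over the 3 groups, 2 of 100 drawn splits reached the 18 genes of the real one, and the highest other also gave 18.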

How the results depend on the processing

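Annotated transcripts only, exon coverage, protein-coding genes only and zeros left out were alternatives added after the results were seen; for every change below the cause was not tested unless stated. Genes called between competent embryo medium and control (5) became 8 without a filter, 3 with a filter at 5 FPKM, 24 with only the 2 groups, 18 with arrayWeights, 8 with annotated transcripts only, 0 with exon coverage by limma and 1 with zeros left out, and ranged from 8 to 21 with a library left out. Between arrested embryo medium and control (8) they became 15 with only the 2 groups, 4 with the transcript of highest mean FPKM and 1 with zeros left out, by removal of those genes, and ranged from 10 to 27. Between the conditioned media (39) they became 19 with failed estimates kept, 22 with annotated transcripts only and 86 with exon coverage, and ranged from 18 to 139. The F test (18) gave 13 with failed estimates kept, 5 with zeros left out, and 19 to 53 with a library left out. Gene lists called (10, 6 and 7 in that order) became 0, 0 and 1 with an estimated correlation and 2 for arrested embryo medium against control with quantile normalization; with a library left out they ranged from 6 to 10, 4 to 12 and 7 to 12. The correlation of the 2 responses was 0.138 with exon coverage. Reversed were Ubl4 with the transcript of highest mean FPKM (0.15 after competent and 0.32 after arrested embryo medium), the ribosomal list after arrested embryo medium with quantile normalization (-0.0033), and the mitochondrial list after arrested embryo medium with only the 2 groups (median 0.46, camera direction turned) and without competent library 1; with a library left out its median ranged from 0.33 to 0.61. The named genes gave 34 calls of 26 genes; of their 813 alternative values 665 kept the call and 146 lost it. Calls of 7 genes were never lost in the settings where they were tested, Muc4, Cd83 and 5 genes listed at 0 in a whole group. Those 5 (Snord23, Sprr2g, SCARNA21, March2 and Syce2) were tested in 22 to 24 settings. Leaving out genes at 0 removes them without counting as a loss, and the other settings start from the same deposited estimates. Their kept calls therefore do not show that the zeros are real. The lists gave 23 calls of 13 lists; of their 575 alternative values at the preset correlation 502 kept the call and 70 lost it, and 9 calls were never lost, of which only that of the estradiol list between the conditioned media also held with an estimated correlation.

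With replicate number as a block, 1 gene was called between competent embryo medium and control, 8 between arrested embryo medium and control, 9 between the conditioned media and 11 in the F test. Residual correlations were -0.029 to 0.21 for libraries of the same number and -0.17 to 0.18 for other numbers. The highest was that of competent library 1 with arrested library 1. In both other groups, 3 of the 9 libraries correlated best with their own number. No strong pairing was seen, but a weak one is not excluded. The block spends degrees of freedom, and the unpaired fit, planned as the main one, was kept. Low depth per gene limits the genes of few FPKM, for which an estimate of 0 and a small value cannot be separated by these data.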

Other observations

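No test in this part was chosen as an explanation; the genes below were picked by the smallest p within lists fixed beforehand, after the results were seen.

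Decidualization markers split by direction between the conditioned media. Alpl, the tissue-nonspecific alkaline phosphatase of the decidual reaction, stood at 10.3 ± 1.83 FPKM in controls, 34.9 ± 7.70 after competent and 11.3 ± 8.26 after arrested embryo medium (n = 3). Hopx, a homeodomain cofactor, stood at 18.4 ± 1.59, 12.7 ± 5.08 and 33.3 ± 11.3. Adjusted over the list alone, Abp1, Alpl (-1.73 ± 0.40) and Wnt4 were lower and Hopx (1.34 ± 0.30), the activin antagonist Fst (1.18) and the TGF beta family member Lefty2 (0.69) were higher after arrested than after competent embryo medium. Against control, Abp1 and Alpl (1.65 ± 0.40) were higher and Lefty2 (-0.73 ± 0.21) lower after competent embryo medium on the same measure. The list as a whole had medians of -0.0074, -0.17 and -0.10 in the comparisons of competent with control, arrested with control and arrested with competent (limma camera adjusted p = 0.568, 0.911 and 0.559).

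Single members of the protease list and of the transporter list differed between the conditioned media, though neither list was called (limma camera adjusted p = 0.312 for each). Klk1, the tissue kallikrein, stood at 195 ± 61.4 FPKM in controls, 195 ± 109 after competent and 55.6 ± 17.7 after arrested embryo medium (n = 3), and Cftr, the chloride channel, at 17.1 ± 3.45, 26.5 ± 3.17 and 12.3 ± 3.43. Adjusted over the protease and sodium channel list alone, Klk1 (-1.71 ± 0.39) and Cftr (-1.07 ± 0.22) were lower after arrested than after competent embryo medium. Adjusted over the transporter list alone, the inositol trisphosphate receptor Itpr2 (1.10) was higher. Scnn1a, the alpha subunit of the epithelial sodium channel, differed by 0.64 ± 0.23 between the conditioned media, 0.55 ± 0.23 between arrested embryo medium and control and -0.09 ± 0.23 between competent embryo medium and control (limma adjusted p = 0.30, 0.78 and 0.99). Ass1, another enzyme of the urea cycle, was lower with Arg1 after arrested than after competent embryo medium when adjusted over the list alone (-1.65 ± 0.38), and the nitrogen list as a whole had a smallest limma camera adjusted p of 0.184.

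Lists not named so far were not called in any comparison. Their smallest limma camera adjusted p over the 3 comparisons was 0.168 for stromal fibroblast, 0.176 for adipocyte, 0.312 for epithelium, 0.344 for uterine gland, 0.356 for neutrophil, 0.444 for squamous epithelium, 0.553 for nerve and glia, 0.603 for mast cell and 0.653 for endothelium markers. Among pathways it was 0.254 for glycolysis, 0.265 for immediate early genes, 0.312 for progesterone-responsive genes and for serine proteases with their inhibitors and sodium channel genes, 0.333 for proteasome subunits, 0.444 for fatty acid synthesis and 0.568 for fatty acid oxidation (limma camera adjusted p). It was 0.57 for the tricarboxylic acid cycle and oxidative phosphorylation, 0.739 for hypoxia and angiogenesis, 0.75 for inflammatory cytokines and 0.816 for apoptosis and p53 targets (limma camera adjusted p). Within the progesterone list, adjusted over the list alone, Gadd45g (-0.76) and Gata2 were lower and Tsc22d3 (0.70) and Ihh higher after arrested than after competent embryo medium.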
